A study of Methanococcus maripaludis with 12 samples.

How the data were processed

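Total RNA from 12 cultures or culture samples of Methanococcus maripaludis S2 was depleted of ribosomal RNA with oligonucleotides made for Methanococcus and sequenced as paired reads of 150 bases, per the labels' protocols. Cultures were grown at 37 °C with 0.4% sodium formate and 10 mM acetate under nitrogen and carbon dioxide. According to the protocols, iron was supplied as mackinawite (an iron sulfide, 10 µM) in general and as iron(II) chloride (25 µM) in experiments with molybdenum disulfide. The harvest hour differed between cultures with molybdenum (24 h) and without (30 h). The labels do not say which iron source the molybdate and no-molybdenum cultures had, so it is not known whether iron source also differed with the groups.

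The deposited values are whole-number counts of reads per gene, with 1 file per library and no normalization. Bowtie2 and HTSeq are named in the submitters' processing notes without versions or settings. The genome build, the annotation, the strand setting and any trimming are not given in the sources used here. Each file has 1786 gene IDs and 5 summary lines, which were left out of library sizes and tests. Relative to all reads counted or summarised in a library, 16.6% to 20.6% were ambiguous between genes, 1.03% to 1.23% fell on no gene and 0.216% to 0.462% were not aligned. The lines for reads of low quality and for reads that align in several places were 0 in every library. How reads from repeated sequences were assigned is therefore not shown, and values of overlapping or near-identical genes are uncertain.

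The name table used here, of another strain of the species, shares 0 of the 1786 IDs, so no ID was given a name. There, 1866 steps between successive tags (99.6%) go to a higher start coordinate. Whether IDs that follow each other here also lie side by side on the S2 chromosome was not checked. Without names, the planned gene lists, their set tests, the values of nitrogenase, molybdenum enzyme and transport genes, and the exclusion of ribosomal RNA genes could not be applied. Any ribosomal RNA genes among the IDs stay in the library sizes.

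Genes were filtered with edgeR's filterByExpr, which left 1771 and removed 15. Library totals were scaled by TMM factors, and CPM values use these scaled totals. A quasi-likelihood model with group as the term was fitted to all 12 libraries together in edgeR 4.0.16 under R 4.3.3, with 9 residual degrees of freedom and robust estimation. The 3 comparisons were molybdate minus no molybdenum, molybdenite minus no molybdenum and molybdenite minus molybdate. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and genes with an adjusted p under 0.05 were called. Standard errors of log2 fold changes were computed as the size of the change divided by the square root of the F statistic. Principal components were computed on log2 CPM with a prior count of 2. Totals of 13683528 to 30304981 counts per library, with 355 or more counts behind every printed gene level, leave the spread between libraries as the main source of error.

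The IDs printed follow a rule fixed before the data were examined, as were the tests and all alternatives except those named as chosen later. It takes called genes with non-overlapping groups and a mean of at least 10 CPM, ranked by the size of the change. Since IDs are unnamed, only the largest rise and the largest fall of each comparison with no molybdenum are printed. Runs of neighbouring IDs stand in for the gene lists. A run was a stretch of at least 3 tested IDs that follow each other in the files and were called in the same direction, and the number of genes in runs was set against 10000 shuffles of the ID order. This use of ID order was chosen after the data had been seen. To allow for the shared libraries without molybdenum, unchanged groups were simulated 50 times and those libraries were split into A with B and C with D.

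The test was checked on simulated counts with 100 genes changed 1.5-fold and 100 changed 2-fold. Simulated genes varied independently, without changes shared by whole libraries, so the rates that follow need not hold for the real counts. For molybdate minus no molybdenum, 82 and 95 of these were recovered among 1769 genes, with 5 false calls. For molybdenite minus no molybdenum, 88 and 96 were recovered among 1771 genes, with 8 false calls. For molybdenite minus molybdate, 84 and 95 were recovered among 1768 genes, with 6 false calls.

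Alternatives were DESeq2 size factors, upper-quartile scaling, library totals alone, the Wald test of DESeq2 1.42.0, limma-voom 3.58.1, no filter, a filter at a mean of 10 CPM, a term for the replicate letter, fits of the 8 libraries compared, each library left out, and glmTreat tests against 1.5-fold and 2-fold changes. Fits without the 3 libraries that stood apart on component 1, and with a term for them, were added after the data had been seen. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.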

Results

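Transcript levels were measured by RNA sequencing in Methanococcus maripaludis S2, a methane-producing archaeon, grown by nitrogen fixation on formate. Nitrogen fixation and parts of methane formation in this organism use enzymes that can hold molybdenum, and the study asked which molybdenum sources the cells can use. Cells passaged 5 times without molybdenum to make them molybdenum-limited were inoculated into medium with no molybdenum, with molybdate (the soluble oxyanion, 5 µM) or with molybdenite (the mineral molybdenum disulfide). Molybdate and molybdenite cultures were harvested at 24 h and cultures without molybdenum at 30 h, all in late log phase according to the labels. There were 12 libraries in 3 groups of 4, lettered A to D. The titles write MoS4 for the group taken here as molybdenite, because molybdenite is the remaining condition that the design text describes. The design text speaks of 9 reactors, 3 per condition, whereas the labels hold 4 libraries per condition. Nothing in the labels ties a library to a reactor, so p-values measure the spread between these libraries, which may be partly technical.

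Counts assigned to genes came to 14964428, 18459585, 16637411 and 23648148 in molybdate libraries A to D. Molybdenite libraries A to D held 21776694, 18999333, 13683528 and 20503877. Libraries A to D without molybdenum held 18244883, 18075448, 16207715 and 30304981. Each library reported 1786 gene IDs, of which 1771 had enough counts to be tested. The files give IDs without gene names, and the name table used here, of another strain of the species, matched 0 of the 1786 IDs. Genes are therefore described by ID, by level and by their neighbours in ID order, and only 4 IDs are printed.

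Libraries of the same group correlated at Spearman's rho of 0.982 to 0.999 across genes, and libraries of different groups at 0.976 to 0.997. The 0.997 was that of molybdate D with molybdenite A. Either of these correlated less with the libraries of its own group, at 0.985 to 0.990. Component 1 of the log2 CPM (counts scaled to a common library size) held 33.5% of the variance and did not follow the groups. It set molybdate D (score 9.80), molybdenite A (10.1) and the no-molybdenum library D (8.25) apart from the other 9 libraries, whose scores lay between -5.97 and -0.652. These 3 libraries, 1 per group, also had the 3 highest counts. Component 2, with 21.8% of the variance, had all 4 libraries without molybdenum below 0 and all 8 libraries with molybdenum above 0. No library pair within a group agreed within sampling noise, with chi-square values per degree of freedom from 20.6 to 376 where sampling noise alone gives 1.

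**Figure D1:**
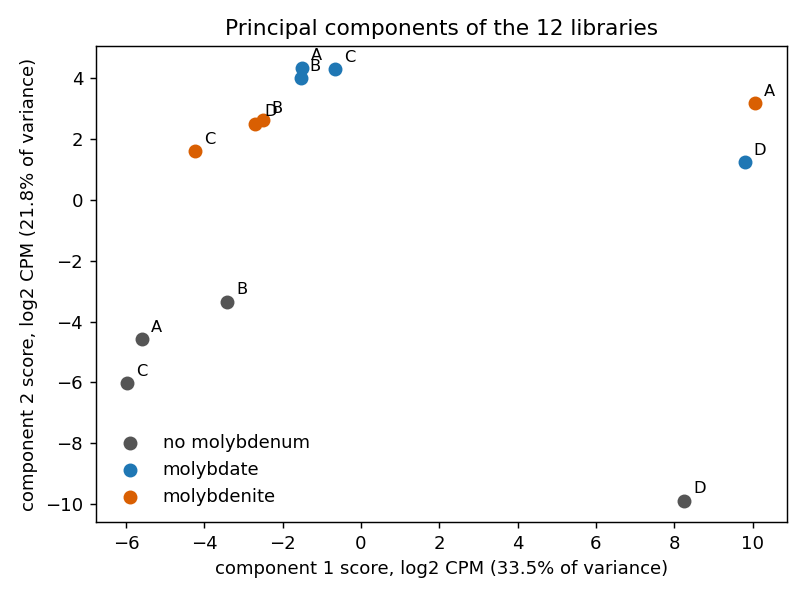
Scores of the 12 libraries on components 1 and 2 of log2 CPM over 1771 genes, with 33.5% and 21.8% of the variance, coloured by group and marked by replicate letter. Molybdate D, molybdenite A and no-molybdenum D lie at 8.25 to 10.1 on component 1 and the other 9 libraries below 0, while component 2 parts the libraries without molybdenum from the rest.

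The comparison of molybdate with no molybdenum asked how the transcripts of molybdenum-limited cells differ when the soluble form is supplied. A run of 13 neighbouring IDs that holds MMP_RS08585 was higher with molybdate at every ID, with log2 fold changes of 0.33 to 1.37 and a median of 1.12. MMP_RS08585 itself stood at 484 ± 113 CPM with molybdate and 188 ± 59.0 CPM without (SD, n = 4 each), a 2.58-fold rise (log2 fold change 1.37 ± 0.23 SE, adjusted p = 0.00513). A run of 5 IDs that holds MMP_RS02680 was also higher, with log2 fold changes of 0.62 to 1.39 and a median of 1.33. MMP_RS02680 had the largest rise of the comparison by the naming rule, from 23.7 ± 3.05 to 62.1 ± 9.34 CPM (SD, n = 4 each), or 2.61-fold (log2 fold change 1.39 ± 0.14 SE, adjusted p = 0.000296). Among genes that fell, MMP_RS05965 had the largest fall, from 323 ± 64.3 to 165 ± 37.4 CPM (SD, n = 4 each), with a log2 fold change of -0.97 ± 0.22 SE (adjusted p = 0.0222).

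MMP_RS05965 lay at the end of a run of 3 IDs that were lower with molybdate, by log2 fold changes of -0.97 to -0.32. A further run of 5 IDs was lower at every ID, with a median of -0.57. In all, 7 runs of 3 or more neighbours were called in the same direction, 4 higher and 3 lower, and they held 35 genes, 23.0% of those called. In a permutation test with 10000 shuffles of the ID order the median was 0 and the highest value 11 (one-sided p = 1e-04, the smallest these shuffles can give). Runs were examined after the data had been seen. In each comparison the shuffles test only whether calls lie together in the ID order, and not whether molybdenum caused them. Of the 6 IDs in the run of MMP_RS06685, which is described with molybdenite, 2 were called lower with molybdate. The median log2 fold change of the 6 with molybdate was -0.44. MMP_RS06685 itself had a log2 fold change of -0.45 ± 0.13 SE (adjusted p = 0.0508, and 0.00988 to 0.137 over all settings). It was called without molybdenite A (adjusted p = 0.0277) and without molybdenite C (adjusted p = 0.0474).

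Over all genes, edgeR's quasi-likelihood test called 152 of 1771 genes (8.58%) at an adjusted p under 0.05, 71 higher and 81 lower with molybdate. Estimated changes of at least 2-fold were found for 13 of them, 13 higher and 0 lower, and the median size among called genes was 1.33-fold. Lower genes of that size numbered 2 with library totals alone and without molybdate B, and 1 without each of molybdate A and no-molybdenum A, B and D. The 4 values of the groups did not overlap for 319 genes (18.0%), against 2.86% by chance. Without the 3 libraries that stood apart, 277 genes were called, 136 of them among the 152. The number called fell to 67, 58 and 75 without molybdate A, B and C and to 71 without the no-molybdenum library C. Genes in runs numbered 19, 19 and 22 without molybdate A, B and C, 64 without molybdenite A and 80 without the 3 apart libraries. The call of MMP_RS05965 was lost without molybdate C (adjusted p = 0.0662) and without the no-molybdenum library C (adjusted p = 0.0617), and 1 of the 3 IDs of its run stayed called without molybdate B. In the further run of 5 lower IDs, 3 stayed called without each of molybdate A, B and C and no-molybdenum D.

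**Figure D2:**
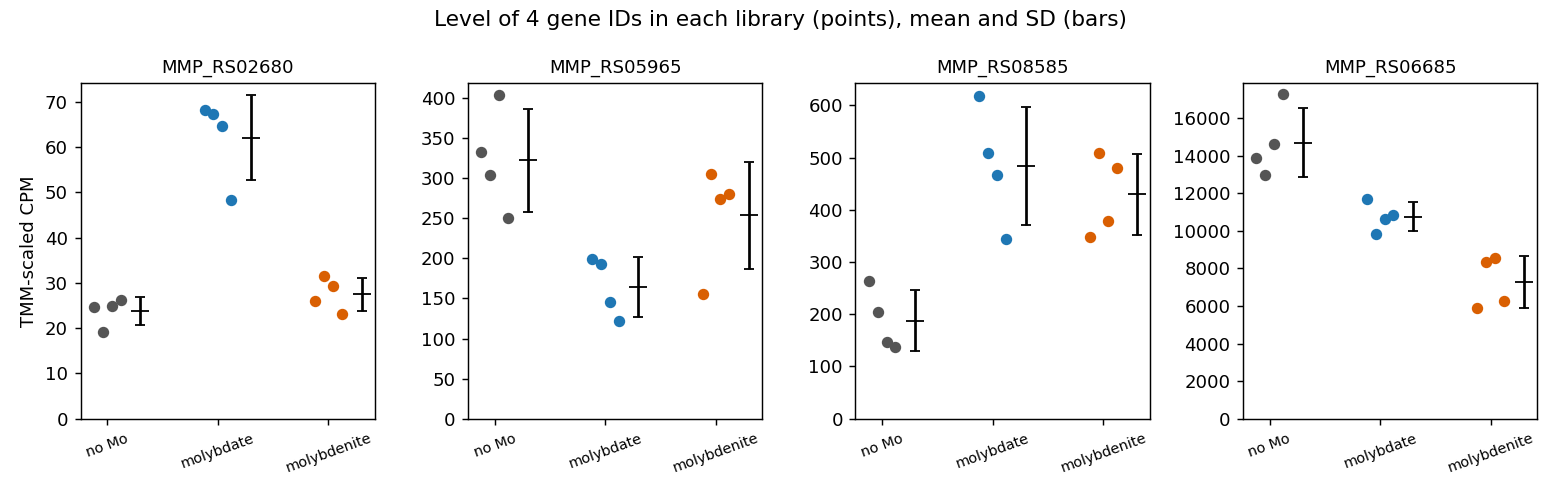
TMM-scaled CPM of 4 gene IDs in each of the 12 libraries (points, by group), with the mean and SD of each group of 4 as bars. All 4 molybdate libraries lie above all 4 libraries without molybdenum for MMP_RS02680 and MMP_RS08585. For MMP_RS06685 all 4 molybdenite libraries lie below all 4 without molybdenum. The naming rule required non-overlapping groups, so these separations of MMP_RS02680 and MMP_RS06685 were fixed by it.

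The comparison of molybdenite with no molybdenum put the same question for the mineral form. The run of 13 IDs with MMP_RS08585 was again higher at every ID, with log2 fold changes of 0.24 to 1.19 and a median of 0.95. MMP_RS08585 reached 429 ± 77.4 CPM (SD, n = 4), 2.29-fold above its level without molybdenum (log2 fold change 1.19 ± 0.22 SE, adjusted p = 0.00671). A run of 6 IDs that holds MMP_RS06685 was lower with molybdenite, with log2 fold changes of -1.02 to -0.53 and a median of -0.79. MMP_RS06685, among the abundant transcripts, went from 14696 ± 1844 to 7261 ± 1388 CPM (SD, n = 4 each), a 2.02-fold fall (log2 fold change -1.02 ± 0.13 SE, adjusted p = 0.00128). A run of 10 other IDs was higher with molybdenite, with log2 fold changes of 0.38 to 0.79 and a median of 0.63, and 3 of these 10 were also called higher with molybdate.

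The run of 5 IDs with MMP_RS02680 had a median log2 fold change of 0.26 with molybdenite, and 2 of the 5 were called higher. MMP_RS02680 itself stood at 27.5 ± 3.70 CPM (SD, n = 4), with a log2 fold change of 0.21 ± 0.14 SE (adjusted p = 0.379). For MMP_RS05965 the level was 254 ± 67.1 CPM (SD, n = 4), with a log2 fold change of -0.35 ± 0.22 SE (adjusted p = 0.348). There were 16 runs of 3 or more neighbours called in the same direction, 6 higher and 10 lower. They held 79 genes, 33.9% of those called, against a median of 3 and a highest value of 19 in the permutation test with 10000 shuffles (one-sided p = 1e-04, the smallest these shuffles can give).

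In total 233 of 1771 genes (13.2%) were called by edgeR at an adjusted p under 0.05, 122 higher and 111 lower with molybdenite. The estimated change was at least 2-fold for 9 of them, 7 higher and 2 lower, and the median size among called genes was 1.31-fold. The 2 falls became 0 without molybdenite A or D and 3 without molybdenite B. They became 1 without no-molybdenum A, no-molybdenum D or the 3 apart libraries. Groups did not overlap for 326 genes (18.4%). Without the 3 libraries that stood apart, 397 genes were called, 219 of them among the 233. The number called fell to 150 and 105 without molybdenite B and D, and to 145 and 154 without no-molybdenum A and B. Genes in runs numbered 42 and 22 without molybdenite B and D, 35, 36 and 51 without no-molybdenum A, B and C, and 191 without the 3 apart libraries. In the run of MMP_RS06685, 3 of the 6 IDs were called without molybdenite D and 4 without each of no-molybdenum A, B and C. Of the 13 IDs with MMP_RS08585, 10 stayed called without each of molybdenite B and D and no-molybdenum C and D. Without molybdenite C or no-molybdenum B, 11 stayed called. The run of 10 kept 7 calls without molybdenite D and 8 without each of molybdenite A and no-molybdenum A and B.

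**Figure D3:**
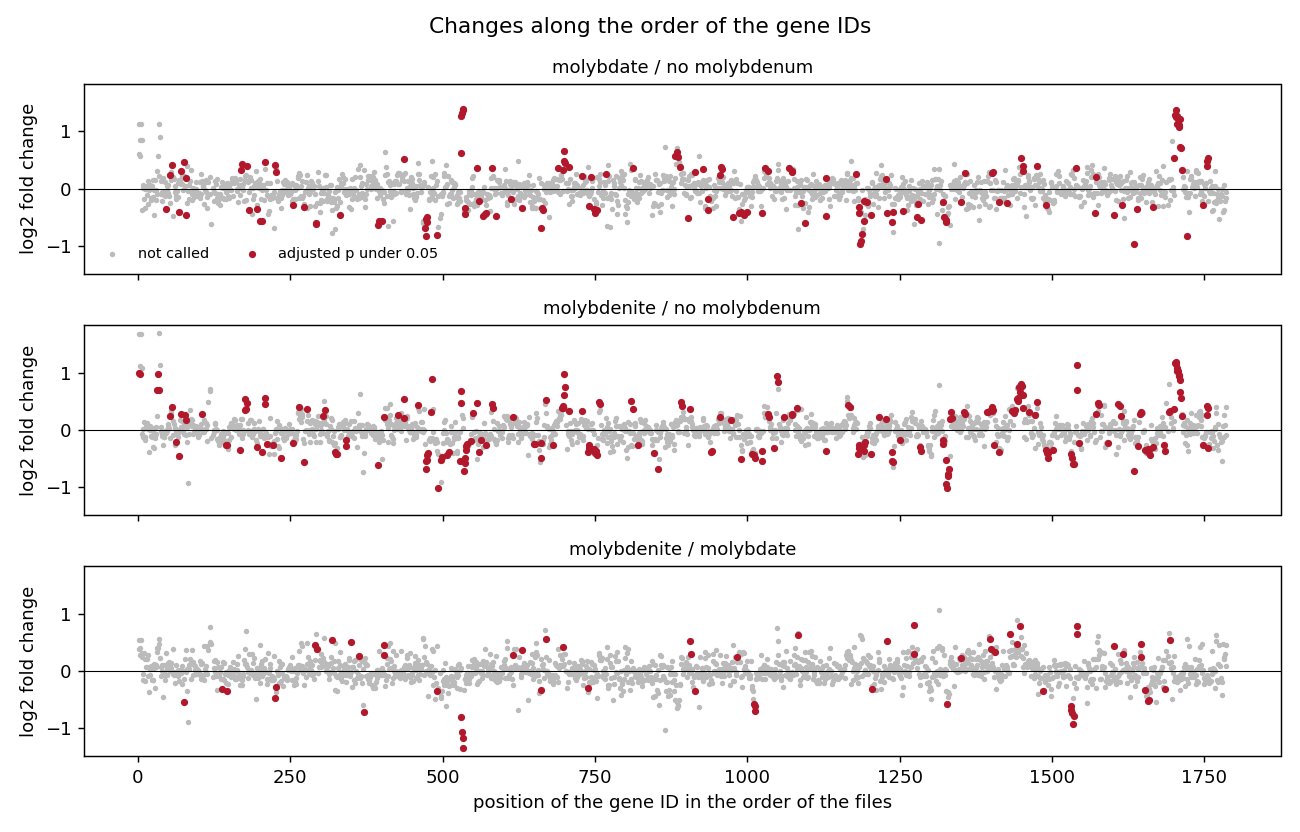
Log2 fold change of each gene ID (vertical axis) against its position in the order of the files (horizontal axis) for the 3 comparisons, with genes at an adjusted p under 0.05 in red. The 13 neighbouring IDs with MMP_RS08585 stand together near the right end in both comparisons with no molybdenum, and IDs that do not pass the test are grey.

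Molybdenite and molybdate cultures were compared directly to ask whether the form of molybdenum made a difference. The run with MMP_RS02680 was lower with molybdenite at 4 neighbouring IDs, with a median log2 fold change of -1.12. MMP_RS02680 differed by a log2 fold change of -1.18 ± 0.14 SE (adjusted p = 0.00342), 2.26-fold. The largest fall by the naming rule, in the same run, was -1.33 ± 0.21 SE (adjusted p = 0.0122), and the largest rise was 0.80 ± 0.20 SE (adjusted p = 0.0447). A separate run of 4 IDs was lower with molybdenite at a median of -0.71. None of the 13 IDs with MMP_RS08585 was called between the forms (median log2 fold change -0.13). MMP_RS08585 differed by -0.17 ± 0.22 SE (adjusted p = 0.685).

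MMP_RS06685 was lower with molybdenite than with molybdate (log2 fold change -0.57 ± 0.13 SE, adjusted p = 0.0341), the only called ID of the 6 in its run. For MMP_RS05965 the difference was 0.62 ± 0.22 SE (adjusted p = 0.130). It was called without molybdenite A (adjusted p = 0.0172) and without the 3 libraries that stood apart (adjusted p = 0.00588), within a range of 0.00588 to 0.326 over all settings. In all, 3 runs of neighbours, each lower with molybdenite, held 11 genes, 18.0% of those called, against at most 6 in the permutation test with 10000 shuffles (one-sided p = 1e-04, the smallest these shuffles can give).

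Between the forms edgeR called 61 of 1771 genes (3.44%) at an adjusted p under 0.05, 32 higher and 29 lower with molybdenite, 3 of them at least 2-fold, 0 higher and 3 lower (1 and 3 without molybdenite A). The median size among called genes was 1.39-fold, and groups did not overlap for 231 genes (13.04%). This count changed strongly when single libraries were left out. It was 2, 25 and 5 without molybdate A, B and C, 20, 4 and 2 without molybdenite B, C and D, 92 and 215 without molybdate D and molybdenite A, and 93 without the no-molybdenum library D. Without the 3 libraries that stood apart it was 410, with all 61 among them, and 85 genes lay in runs. Genes in runs numbered 0 without molybdate A, molybdate C, molybdenite C or molybdenite D, 4 without molybdate B and 26 without molybdenite A. In the run with MMP_RS02680, 1 of the 4 IDs stayed called without molybdate A, molybdenite C or molybdenite D, and 2 without molybdate C. The separate run of 4 kept 0 calls without molybdate A, molybdate C, molybdenite C or molybdenite D. Its median log2 fold change in these fits was -0.65, -0.69, -0.68 and -0.65, against -0.71 with all libraries. MMP_RS06685 lost its call without molybdate A, B or C and without molybdenite B, C or D, with adjusted p from 0.0522 to 0.128 over these fits and 2 other settings. The 3 genes changed at least 2-fold became 1 without molybdate A, molybdenite C or molybdenite D.

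The changes with both forms were then set side by side. Of the called genes, 85 changed in the same direction in both comparisons, 47 higher and 38 lower, and 0 changed in opposite directions. These include all 13 IDs of the run with MMP_RS08585 and 4 IDs of the run of 5 that was lower with molybdate at a median of -0.57. Molybdate alone called 67 genes and molybdenite alone 148, but a call in 1 comparison is not a difference between the forms. The direct test between the forms called 12 of the 152 genes called with molybdate and 28 of the 233 called with molybdenite, with 1 gene in both.

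Both comparisons share the 4 libraries without molybdenum, which by itself makes their changes alike. Independent lists of the same sizes would share 9.97 genes. Simulated groups without any change, set against these libraries in 50 data sets, gave 0 shared calls, but only 0.04 genes on average were called with simulated molybdate, so that 0 gives no measure of what shared libraries add to 85. Across genes, which are not independent replicates, log2 fold changes of the comparisons correlated at r = 0.61, against 0.49 in the simulations. Their covariance was 0.0403 against 0.0109 simulated, a difference of 0.0294. The simulated genes varied independently of each other, without the component that set 3 libraries apart, so this difference is only a rough guide. With no-molybdenum A and B used for molybdate and C and D for molybdenite, r was 0.36 and 18 genes were shared by lists of 36 and 150 calls. With the pairs exchanged, r was 0.25 and 34 genes were shared by lists of 186 and 153. The covariances were 0.0277 and, with the pairs exchanged, 0.0213. Here the comparisons share no libraries, so 0.36 and 0.25 are not to be set against the simulated 0.49. These fits have 2 libraries without molybdenum per comparison, so their lists also differ in size from 152 and 233. The count of 85 became 44, 36 and 53 without molybdate A, B and C, 55 and 47 without molybdenite B and D, and 51 and 43 without no-molybdenum A and C. Without the 3 libraries that stood apart it was 114.

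**Figure D4:**
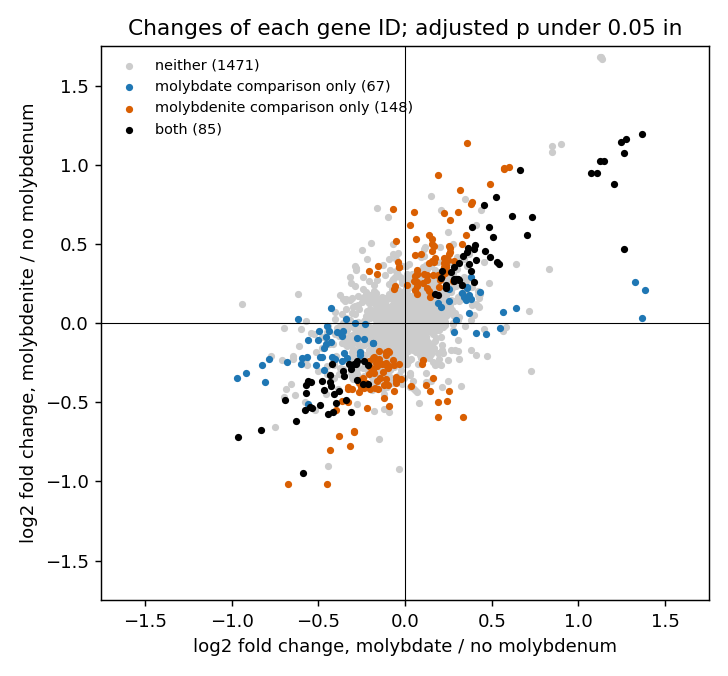
Log2 fold change with molybdenite (vertical axis) against that with molybdate (horizontal axis), each relative to no molybdenum, for 1771 gene IDs coloured by the comparisons in which the adjusted p was under 0.05. The 85 genes called in both lie in the quadrants of equal sign, 47 higher and 38 lower.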

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

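The tests of exchanged labels, mixture, batch, harvest hour and iron source, and the fits without the 3 libraries that stood apart or with a term for them, were chosen after the results were seen.

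Library D without molybdenum held 30304981 counts, against 16207715 to 18244883 in the other 3 of its group. On component 1, molybdate D scored 9.80 and molybdenite A 10.1, far from the others of their groups, and on component 2 molybdate D scored 1.25 where the other 3 molybdate libraries scored 4.01 to 4.35. These were 4 outlying values among 39 groups of 4 examined, where chance alone marks about 1 group in 20. The effect of molybdenite differed from that of molybdate in the direct test for MMP_RS02680 (log2 -1.18), for MMP_RS06685 (log2 -0.57) and for 61 genes in all. When the 8 libraries of a comparison were divided in all 35 ways into 4 and 4, only the real division gave as many calls in each comparison (1 of 35). The real division parts the libraries that stood apart, as 20 of the 35 do, and among these 20 it was again the only 1, a share that cannot go under 0.05. The real and the highest other counts were 152 and 0 for molybdate, 233 and 0 for molybdenite, and 61 and 1 between the forms.

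Molybdate D, molybdenite A and no-molybdenum D lay 8.90 units above the other 9 libraries on component 1. With group in the model, edgeR called 858 genes (48.4%) between these 3 libraries and the others. The 3 were picked by component 1 of the same values, so the 858 calls describe the gap and do not test it. Depth through counting noise and a few abundant genes are argued against, because the gap was 8.66 after thinning every library to 13683528 counts and 8.89 without the 50 most abundant genes. An exchanged label of no-molybdenum D is argued against, because differences of the 3 libraries followed the group differences of the other 9 with slopes of 0.86 for molybdate and 0.88 for molybdenite, above the bound of 0.5 that had been set for all 3 slopes together before the parts were separated. Between the forms the slope of 0.32 missed that bound, but a full exchange of molybdate D and molybdenite A is argued against, because 331 of 410 genes (80.7%) kept the labelled direction and 9 held-out pairs of the other libraries would give slopes of -0.47 or lower if exchanged. A partial mixture of these 2 libraries cannot be told apart from a smaller difference between them. The slope of 0.32 lay under the lowest held-out slope (0.47) by less than the SD of 0.254. The held-out pairs kept 94.1% to 98.8% of directions. A separate culture, extraction or library batch may also be the source, but the labels name no batch. The other 9 libraries equal in number the 9 reactors of the design text, but no label ties a library to a reactor. No biological explanation was tested.

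All genes called against no molybdenum, 152 with molybdate and 233 with molybdenite, could reflect the supply of molybdenum or the hour of harvest. This includes the 85 genes that changed in the same direction with both forms. The same holds for component 2 and for the share of reads that fell on no gene. Every culture with molybdenum was harvested at 24 h and every culture without it at 30 h. No group separates the hour from the molybdenum, so these explanations cannot be told apart. How many of the 85 come from the shared no-molybdenum libraries is not known, since dividing those libraries gave 18 and 34 shared genes but also changed the lists to 36 and 150 and to 186 and 153 calls.

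For the genes that differ between the forms, the hour of harvest is argued against as a cause, because the labels give 24 h for both groups. Between these groups 61 genes were called, and the other 34 divisions gave at most 1. Those divisions bear on the difference between the groups and not on the hour, for which only the labels speak. The labels do not say whether the iron source differed between the forms. If it did, it may account for part or all of the difference, as may the form of molybdenum, and no group separates them. If the iron source also differed from that of the cultures without molybdenum, the same holds for the comparison of molybdenite with them. Without the 3 libraries that stood apart 410 genes were called, with all 61 among them. The 61 calls therefore do not depend on these 3 libraries. The 3 were picked by component 1 of the same values, so the rise to 410 is no test of their effect.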

How the results depend on the processing

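The fits without the 3 libraries that stood apart and with a term for them were chosen after the data were seen. Counts are given for molybdate, molybdenite and the direct comparison in that order (152, 233 and 61 as reported), then for genes shared by both forms (85). No setting reversed the direction of a printed gene.

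Scaling by DESeq2 factors gave 150, 231 and 63, upper quartiles 145, 231 and 59, limma-voom 152, 233 and 61, no filter 152, 232 and 59, and a mean of at least 10 CPM 152, 236 and 60. With library totals alone the direct comparison rose to 102, of which 76.5% were higher with molybdenite against 52.5% as reported, and the counts against no molybdenum were 212 and 230. The 212 molybdate calls were 52 higher and 160 lower (24.5% higher), against 71 and 81 (46.7%). With upper quartiles 23 of the direct calls were higher and 36 lower, against 32 and 29. The DESeq2 Wald test gave 250, 339 and 191, with 129 shared, and the cause was not tested. Fits of the 8 libraries compared, which have fewer samples, gave 101, 154 and 39, with 44 shared. Without the 3 apart libraries the counts were 277, 397 and 410, with 5 direct changes of at least 2-fold. With a term for them the counts were 452, 539 and 364, with 227 shared, and all genes called as reported stayed called. Divided controls gave 18 and 34 shared genes.

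Leaving out each library in turn gave 58 to 212, 105 to 254 and 2 to 215 calls, and 36 to 78 shared genes. Changes of at least 2-fold ranged over 11 to 14, 8 to 12 and 1 to 4. In edgeR's glmTreat test against a 1.5-fold change, 5, 0 and 0 genes passed, with 22, 28 and 10 at an unadjusted p under 0.05. Against a 2-fold change 0, 0 and 0 passed, with 8, 1 and 2 unadjusted. The counts of at least 2-fold therefore rest on estimates and not on a test of that size.

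Replicate letters were not taken as pairs, because the labels do not tie them and not every pair of equal letter deviated together. Deviations from group means correlated above 0.1 in 7 of 12 such pairs (-0.48 to 0.82). All 3 pairs of letter C were among them (0.28 to 0.47), and 7 of 12 libraries correlated best with their own letter where 3 are expected by chance, a hint from the data and not from the design. Molybdenite A went with the D libraries (0.66 and 0.68), while molybdenite D correlated at 0.30 with molybdate A and at 0.35 with both molybdate B and no-molybdenum A. With the letter as a block, 153, 220 and 79 genes were called, 128, 196 and 53 of them as before, and 76 were shared. The block used the letters as labelled, and no fit was run with those of molybdenite A and D exchanged. Of the printed genes only MMP_RS06685 between the forms lost its call under the block (adjusted p = 0.0553).

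Over 276 fits of the 4 printed genes, 255 kept their side of the threshold, 10 lost a call and 11 gained one. Those lost were MMP_RS05965 with molybdate in 2 fits and MMP_RS06685 between the forms in 8. Those gained were MMP_RS06685 with molybdate in 6 fits (adjusted p from 0.00988 to 0.0474), MMP_RS05965 between the forms in 4 (0.00588 to 0.0482) and MMP_RS05965 with molybdenite in 1 (0.0279, with the term for the apart libraries). Fits with ribosomal RNA genes kept, and the alternatives for gene list tests, were not run because the name table used here matched no ID. Depth limits little at 13683528 counts or more.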

Other observations

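All observations here were made and their tests chosen after the data were seen.

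A stretch of 4 neighbouring IDs among the 20 most abundant transcripts took 4.13% ± 0.869 of scaled counts without molybdenum, 6.39% ± 0.778 with molybdate and 4.23% ± 0.836 with molybdenite (SD, n = 4 each). With molybdate 2 of the 4 were called higher than without molybdenum, and the 4 adjusted p-values lay between 0.0162 and 0.0580 (median log2 fold change 0.61). With molybdenite none was called (median 0.03), and between the forms none was called either (median -0.59, adjusted p from 0.0510 to 0.111). The most abundant ID of all took 3.43% of counts on average.

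A set of 3 IDs had nearly equal counts in every library (chi-square per degree of freedom of 0.533 to 2.24), while their mean level ranged from 92.1 CPM in molybdenite D to 1225 CPM in molybdenite A, 13.3-fold. A further set of 3 behaved likewise, from 81.6 CPM in no-molybdenum C to 585 CPM in molybdenite A. By ID number, each ID of the further set lies close to an ID of the first, so the sets may not be separate observations. They came from 443 pairs with totals within 1.1-fold among 134 IDs that varied at least 2-fold between libraries. The first set averaged 506 ± 497 CPM with molybdenite and 158 ± 71.4 CPM without molybdenum (SD, n = 4 each), a median log2 fold change of 1.68 that rested on molybdenite A. Without that library the molybdenite mean was 267 ± 162 CPM (SD, n = 3), and the median log2 fold change 0.76. The median between the forms went from 0.55 to -0.38 for the first set and from 0.24 to -0.48 for the further set. None of the 6 IDs was called in any comparison by edgeR with all 12 libraries (smallest adjusted p = 0.0840), and 1 was called higher with molybdate without molybdenite A (adjusted p = 0.0491). Together the 6 IDs took 0.0610% to 0.553% of scaled counts. Molybdenite A is among the 3 libraries that stood apart. Whether the sequences of these IDs are alike, and whether they are ribosomal RNA genes, whose levels depend on the depletion, was not checked, so their levels are not shown to be a response of transcripts to molybdenum.

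The share of reads that fell on no gene was 1.20% ± 0.0264 without molybdenum, 1.06% ± 0.0225 with molybdate and 1.09% ± 0.0214 with molybdenite (SD, n = 4 each). The 4 libraries without molybdenum were higher than the other 8 by 0.128 percentage points (exact permutation test over 495 arrangements, two-sided, p = 0.00202, the smallest it can give). Where on the genome these reads fall was not analysed here.

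Log2 fold changes of IDs next to each other in the files correlated across genes at r = 0.46 with molybdate, 0.65 with molybdenite and 0.41 between the forms, where the highest of 10000 shuffled orders gave 0.101, 0.0926 and 0.0859. At a distance of 10 IDs the values were 0.02, 0.08 and 0.07. A random order of the changes is argued against, and shared transcription of neighbouring genes could underlie the 0.41 or more, which was not tested because the positions and strands of the genes were not used here.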
